A study of Homo sapiens with 4 samples.

How the data were processed

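Gene expression was measured in HCT116, a human colorectal cancer cell line, 72 hours after transfection with an empty vector or with a vector expressing ZNF582-AS1, with 2 samples per group and 1 array per sample. Per the labels' protocols, total RNA was column-purified and 100 ng was labelled with Cy3 by a low-input amplification kit for one-colour arrays. The labels number the samples 1 and 2 within each group and do not say whether they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. All 4 arrays lay on 1 slide with 1 scan, the empty vector samples at positions 1 and 2 and the ZNF582-AS1 samples at positions 3 and 4, so that no slide block could be fitted and position was not separable from group.

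Spot intensities were extracted with Agilent Feature Extraction 10.7.3.1, per the file headers, and each deposited intensity used here was the processed signal, from which the software had subtracted a spatially fitted background and removed a multiplicative trend. The deposited series table held intensities equal to these signals within a rounding tolerance of 0.6% on all 62976 rows of each array, on a linear scale, with no centring between arrays. Its column medians were 14.6 and 14.0 for the empty vector arrays and 12.9 and 13.3 for the ZNF582-AS1 arrays. No array had a saturated spot among its 58717 non-control spots, and 48.5% to 49.3% of these spots were well above background. The mean raw signal of the negative controls was 97.5 for empty vector sample 1 and 45.3 for empty vector sample 2. It was 43.7 and 44.5 for ZNF582-AS1 samples 1 and 2. The number of arrays limits the precision.

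Control spots and spots marked as outliers were left out, and spots of the same probe were averaged. The log2 intensity of each array was centred on its 75th percentile over the 21525 probes well above background on all 4 arrays, because under 50% of the probes were detected. Of 50599 probes, 22445 were well above background on both arrays of at least 1 group and were kept. Probe names were brought up to date through a RefSeq gene table, which matched 28174 probes by accession and 4043 by symbol, and the array's own name was kept for 18382 probes. That table lists ZNF582-AS1 as ZNF582-DT, and the array calls it LOC386758. Probe coordinates are those of the files, on hg19. The probe with the highest mean over all 4 arrays stood for a gene, which gave 17065 genes.

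Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. The fit had 2 residual degrees of freedom and a prior worth 1.92 more. For a probe well above background on neither array of a group, the fold is given as a lower bound. It was taken between the group means of normalized log2 values. Before this, each dim value was raised, where lower, to the lowest signal among probes well above background on that array. Where no dim value was lower, the fold is an estimate that rests partly on background. The limma p of such probes tests the log2 difference without this raising, not the bound. Where a probe was well above background on 1 of 2 arrays of a group, its log2 value is given with that said, and rests partly on background. Gene lists were compared with camera at a preset correlation of 0.01 between genes, beside camera with an estimated correlation and fry, with Benjamini-Hochberg adjustment over the 29 lists. Log2 fold changes are those of the ZNF582-AS1 vector over the empty vector, with the standard error of the limma fit.

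The design, the 29 gene lists, the rule for named genes and the main alternatives were fixed before the data were examined. The rule named ZNF582-AS1 and ZNF582, then, among genes with a RefSeq symbol, an adjusted p under 0.05 and groups that did not overlap, the 12 with the largest fold in each direction, filled up to 12 by the smallest p among genes whose groups did not overlap. In each list it named the 3 members with the smallest p, and 5 in lists called by camera, and some of these are not reported here. Alternatives were other background corrections, scalings, probe filters, probe choices, variance priors and thresholds, the replicate number as a block, and the fit without each array.

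The surface of the arrays was mapped without use of the groups, after large changes had been seen to lie side by side. A spot was counted as lying in a disturbed patch where at least 25% of the dim spots (log2 intensity under 5.5) within 150 µm varied by over 2 on the log2 scale across the 4 arrays, and 3256 non-control spots, 5.55%, did. The patch rule enters an alternative only, and spots in patches were kept in the comparison.

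The tests were checked on data simulated for the ZNF582-AS1 vector against the empty vector, with 17065 genes, 200 of them changed, in 10 runs. Of the changed genes, 7.6% were called at a log2 change of 0.5, 77.8% at 1, 91.2% at 2 and 97.4% at 4. A list of 30 genes shifted by 0.07 was called in 9 of 10 runs, and an unshifted list in 0. The simulated genes varied independently, so this cannot show how the list test behaves where genes are correlated. The shares of changed genes called hold for data with 200 changed genes only. Tables were handled with the data.table package (version 1.17.8) and figures drawn with matplotlib 3.10.9.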

Results

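The series concerns long noncoding RNA genes silenced by DNA methylation in colorectal cancer, and the arrays address what happens to the transcriptome when one of them, ZNF582-AS1, is expressed again. HCT116 cells carried an empty vector in 2 samples and a ZNF582-AS1 expression vector in 2 samples, and RNA was taken 72 hours after transfection. Each array gave 58717 non-control intensities. Replicates lay close together, with a median absolute log2 difference over the 17065 genes of 0.0626 between the empty vector arrays and 0.0837 between the ZNF582-AS1 arrays. Pairs of arrays from different groups differed by 0.0806 to 0.109.

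ZNF582-AS1 rose from below detection to a clear signal in both transfected samples. Its brightest probe (A_33_P3501900, chromosome 19, 56910479 to 56910538 on hg19) was not well above background in either empty vector sample and was at least 45.2-fold higher with the vector (limma adjusted p = 0.0403). The processed intensities were 5.22 and 8.11 with the empty vector and 789 and 802 with the ZNF582-AS1 vector. Since the empty vector side was not above background, the log2 difference behind this test, 6.95, does not measure the size of the rise, and the value was 3.70 with normexp background correction and 5.94 for the mean of the gene's probes. The gene did not pass with quantile normalization (limma adjusted p = 0.0522), without a filter on dim probes (0.411), or without ZNF582-AS1 replicate 1 (0.255) or replicate 2 (0.395), although both its probes were detected on both ZNF582-AS1 arrays only. With the replicate number as a block the gene did not pass either (limma adjusted p = 0.172). A second ZNF582-AS1 probe (56905683 to 56905742) was at least 6.92-fold higher, with intensities of 4.14 and 3.95 against 127 and 116 (limma adjusted p = 0.00748 over all kept probes). A probe that the array assigns to the lincRNA locus XLOC_013167, chosen after its values were seen, lies 111 bp past the end of the brightest probe (56910650 to 56910709) and was at least 11.4-fold higher (limma adjusted p = 0.00128). The tests of these 2 probes used log2 differences of 4.93 and 5.57, which do not measure the size of the rise either. XLOC_013167 did not pass without a filter on dim probes (limma adjusted p = 0.0949) or with the replicate number as a block (0.0635). The other XLOC_013167 probe (56906111 to 56906170) was not well above background on any array.

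ZNF582, the zinc finger gene beside ZNF582-AS1, was not detected. Neither of its 2 probes (chromosome 19, 56894702 to 56894761 and 56895538 to 56895597) was well above background on any array, so no fold is given. Their intensities lay between 3.70 and 5.43.

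**Figure D1:**
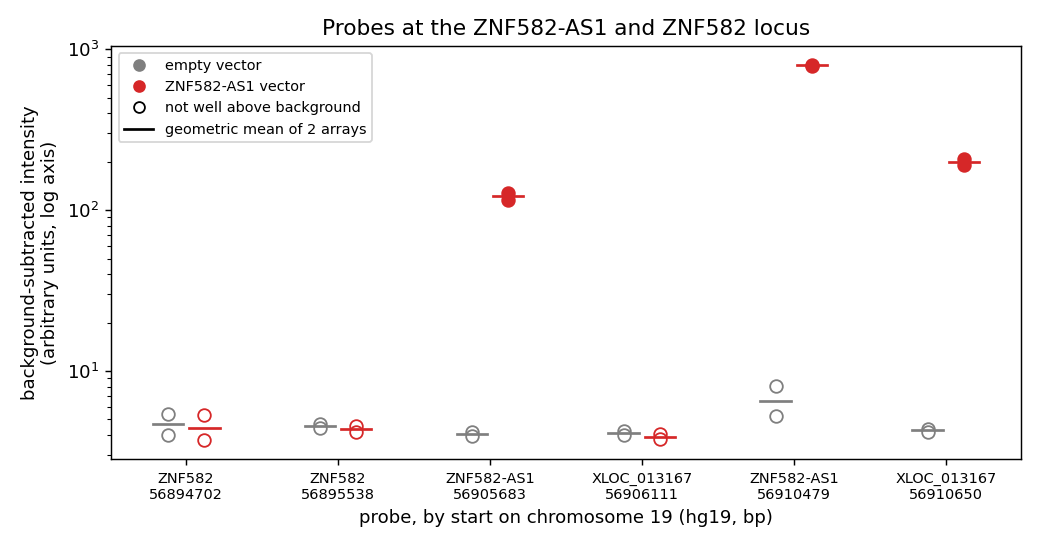
Processed intensity (arbitrary units, log axis) of the 6 probes for ZNF582, ZNF582-AS1 and XLOC_013167, ordered by start on chromosome 19 (hg19), with a point per array, open where the probe was not well above background, and a bar at the geometric mean of 2 arrays. The 3 probes from 56905683, 56910479 and 56910650 lie at 116 to 802 with the ZNF582-AS1 vector and below 9 with the empty vector.

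Beyond its own locus, ZNF582-AS1 was accompanied by few changes that passed the test. Of 17065 genes, 3 were higher and 1 was lower in the limma fit at an adjusted p under 0.05. The higher genes were ZNF582-AS1, XLOC_013167 and XLOC_013980, a lincRNA locus on chromosome 21 (46667014 to 46667073), with a log2 fold change of 1.63 ± 0.05 (SE, n = 2 per group, limma adjusted p = 0.0305), named after its values were seen. The lower gene was LINC01622, a long noncoding RNA on chromosome 6 (1068840 to 1068899), which was not well above background with the ZNF582-AS1 vector and was at least 1.56-fold lower (limma adjusted p = 0.0305). The test of LINC01622 used a log2 difference of -2.67. Since its ZNF582-AS1 side was not above background, that difference does not measure the size of the fall. The probe of XLOC_013980 lay in a disturbed patch of the array surface, and without the spots in such patches 2 genes were higher and 1 was lower. At an unadjusted p under 0.05, 601 genes were higher and 1450 lower, a split that became 1035 and 1010 with quantile normalization and 1011 and 1113 with scaling on all probes. The 2 groups did not overlap in 8147 genes, 47.7%, where chance gives 33.3%. The counts moved with the settings, to 7 higher and 34 lower with normexp background correction, and to 29 and 156 with an intensity trend in the prior variance. Over probes well above background on all arrays the counts were 1 and 0. Without a filter on dim probes, or with the replicate number as a block, the counts were 0 and 0. They were 0 and 0 without either ZNF582-AS1 replicate, 2 and 5 without empty vector replicate 1, and 2 and 9 without empty vector replicate 2, with LINC01622 (limma adjusted p = 0.0707 to 0.255) and XLOC_013980 (0.121 to 0.332) not passing in any of these 4 fits.

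The other 11 genes with the smallest p on the higher side did not pass (limma adjusted p = 0.0643 for POM121L1P, and above that up to 0.236 for the rest). Most were dim. POM121L1P, a pseudogene, had a log2 fold change of 1.25 ± 0.06 (SE, n = 2 per group). USP51, a ubiquitin-specific protease gene, was not well above background with the empty vector and had a bound of at least 6.74-fold, and C16orf89 had a log2 fold change of 2.33 ± 0.24. The probes of all 3 of these genes lay in disturbed patches. Among genes outside patches, 5 were not well above background with the empty vector. Bounds were at least 1.83-fold for GRIN2B, an NMDA receptor subunit, 1.26-fold for DCHS2, a cadherin, and 1.36-fold for CPEB3, an RNA-binding translational regulator. For RAPGEFL1, a Rap exchange factor-like gene, and SYT2, a synaptotagmin, no dim value was raised. Their folds of 1.42 and 1.70 are estimates that rest partly on background, not bounds. The long noncoding RNA PAPOLA-DT, well above background on 1 of 2 empty vector arrays, had a log2 fold change of 0.64 ± 0.06. ULBP3, a ligand of the NKG2D receptor, had 0.36 ± 0.05, and KRTAP6-3, a keratin-associated protein gene, 0.54 ± 0.07.

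On the lower side, small noncoding RNAs stood among the 11 further genes with the smallest p, none of which passed (the lowest limma adjusted p was 0.0643, for CCDC196). SNORA12, a box H/ACA small nucleolar RNA, had a log2 fold change of -1.09 ± 0.06 (SE, n = 2 per group), and SNORD15B, a box C/D small nucleolar RNA, had -0.63 ± 0.05. RNU4ATAC, a small nuclear RNA of the minor spliceosome, had -0.90 ± 0.07, and SCARNA18, a Cajal body RNA, had -0.89 ± 0.07. None of these 4 probes lay in a disturbed patch. Protein-coding genes outside patches were ADAMTS10, a secreted metalloprotease (-0.64 ± 0.05), PAQR6, a membrane progesterone receptor (-0.58 ± 0.05), VSIG8, an immunoglobulin-domain gene (-0.62 ± 0.05), and GOLGA8F, a golgin not well above background with the ZNF582-AS1 vector and at least 1.46-fold lower. CCDC196, GRAP2, an adaptor of T-cell receptor signalling, and TMEM51-AS1 were not well above background with the ZNF582-AS1 vector and had bounds of at least 8.40-fold, 3.51-fold and 2.86-fold. Their probes lay in a disturbed patch.

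The largest changes lay side by side on the array. Outside the ZNF582-AS1 locus, 29 spots of kept probes changed at least 4-fold, 11 higher and 18 lower. Of these, 65.5% had another spot changed at least 4-fold in the same direction within 150 µm, and 75.9% lay in disturbed patches, against 5.43% of all spots of kept probes, where a patch is itself defined by varying dim spots within that distance. The 3 probes of the ZNF582-AS1 locus that rose lay 1.86 to 4.32 mm apart, outside such patches.

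**Figure D2:**
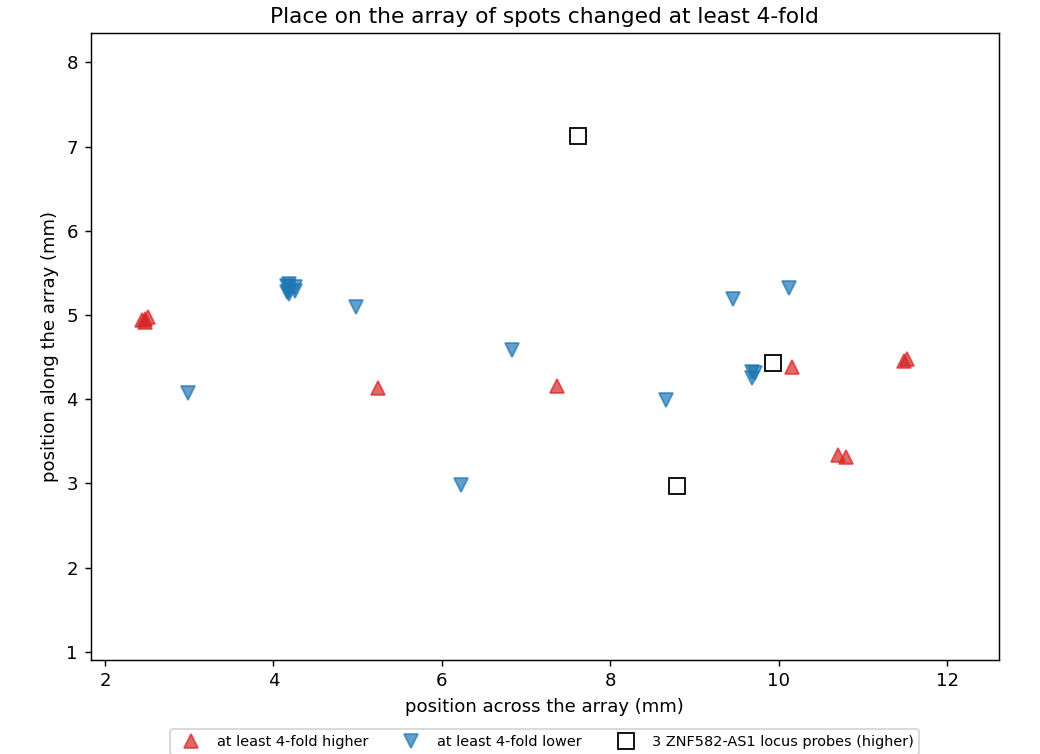
Place on the array (mm) of the 29 spots changed at least 4-fold, pointing up where higher and down where lower with the ZNF582-AS1 vector, and of the 3 ZNF582-AS1 locus probes (squares). Many of the 29 lie in small clusters of 1 direction, and the squares lie apart from each other.

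Camera with the preset correlation called 2 of the 29 lists, both of growth-related genes. The list of ribosome biogenesis genes, many of them MYC targets, had 24 of 28 members positive and a median log2 fold change of 0.07 (camera adjusted p = 0.00112, and adjusted p = 0.699 with an estimated correlation). The list of the G1/S transition and DNA replication had 28 of 34 positive and a median of 0.06 (camera adjusted p = 0.00286, and adjusted p = 0.699 with an estimated correlation). In fry no list passed, the lowest adjusted p being 0.0601 for the ribosome biogenesis, mesenchymal and intestinal differentiation lists, and the replication list had 0.215. No member passed in limma, over all genes or adjusted over the list alone. The ribosome biogenesis members with the smallest p were RRS1 (0.16 ± 0.05, log2 ± SE, n = 2 per group), NOP58 (0.14 ± 0.05), RRP12 (0.19 ± 0.07), NOP16 (0.11 ± 0.05) and WDR43 (0.10 ± 0.05). In the replication list they included CCNE1, which encodes cyclin E1 (0.16 ± 0.05), the replication factor RFC3 (0.16 ± 0.06, in a disturbed patch), GINS2 (0.12 ± 0.05) and UHRF1, which recruits the maintenance DNA methyltransferase (0.13 ± 0.05). The replication list lost its call with quantile normalization, where its median stayed at 0.06 (adjusted p = 0.0659), and without empty vector replicate 2, where its median was 0.03 (adjusted p = 0.0506).

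**Figure D3:**
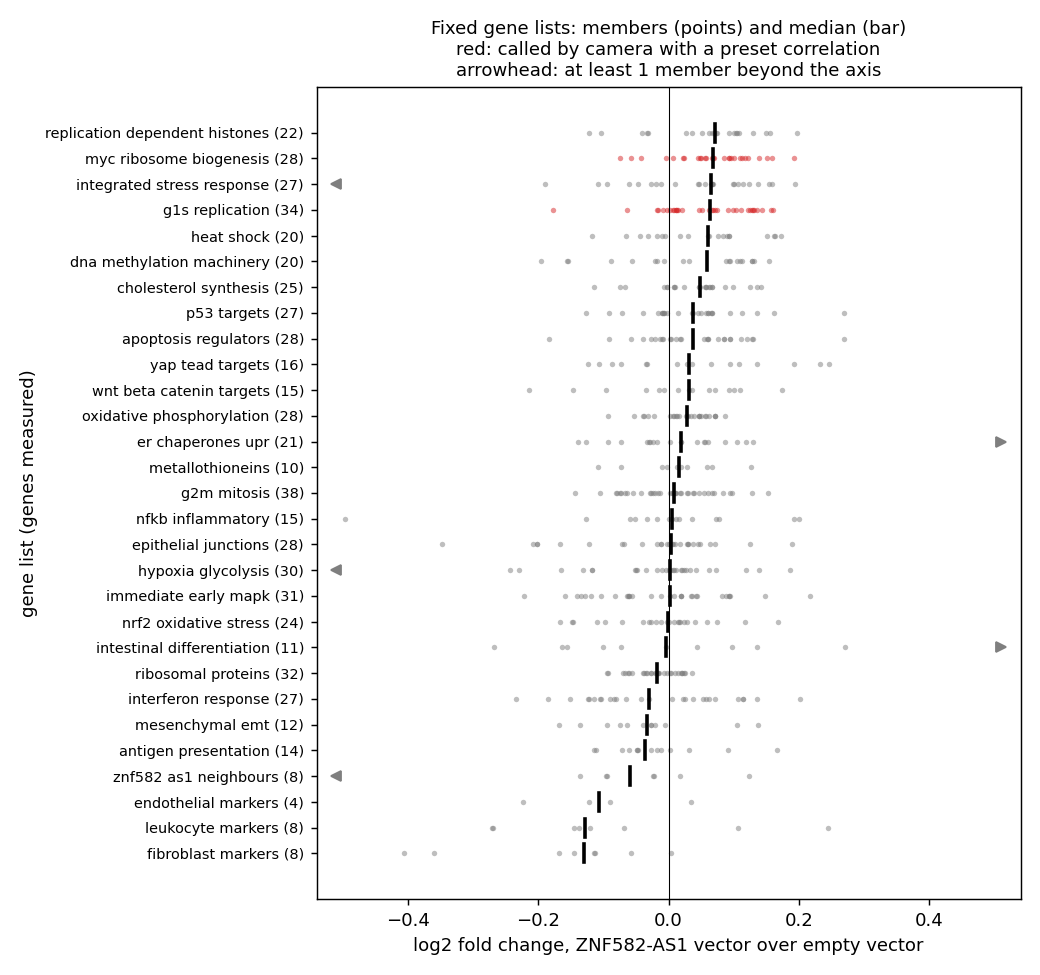
Log2 fold change of the members (points) and the median (bar) of each of the 29 fixed lists, ZNF582-AS1 vector over empty vector, with the number of genes measured in brackets. The lists called by camera with a preset correlation, in red, have medians of 0.07 and 0.06, and all medians lie between -0.13 and 0.07.

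The remaining 27 lists were not called, and no member of any list passed over all genes. Values below are log2 fold changes ± SE with n = 2 per group. Replication-dependent histone genes had 17 of 22 positive and a median of 0.07 (camera adjusted p = 0.0786), which ran from -0.02 to 0.17 as each array was left out and was called without empty vector replicate 2 (0.13, adjusted p = 0.0133) and without ZNF582-AS1 vector replicate 2 (0.17, adjusted p = 4.76e-05), with H2BC4 at 0.20 ± 0.09, H2BC14 at 0.15 ± 0.07 and H4C2 at -0.10 ± 0.05. Mitotic G2/M genes had 22 of 38 positive and a median of 0.01 (camera adjusted p = 0.676), with CCNA2, cyclin A2, at 0.15 ± 0.05, ESPL1 at -0.10 ± 0.05 and NEK2, in a disturbed patch, at 0.13 ± 0.06. Ribosomal protein genes had 10 of 32 positive and a median of -0.02 (camera adjusted p = 0.729), with RPS2 at -0.09 ± 0.06, RPLP1 at -0.09 ± 0.06 and RPLP0, in a disturbed patch, at -0.07 ± 0.05. For nuclear-encoded oxidative phosphorylation genes 22 of 28 were positive with a median of 0.03 (camera adjusted p = 0.140), and NDUFS3 had 0.09 ± 0.05, ATP5F1A 0.07 ± 0.05 and CYCS 0.07 ± 0.05. Cholesterol synthesis genes had 19 of 25 positive and a median of 0.05 (camera adjusted p = 0.0786), with IDI1 at 0.14 ± 0.05, NSDHL at 0.13 ± 0.05 and STARD4 at 0.14 ± 0.05. That list was called with scaling on all probes (camera adjusted p = 0.0447), without a filter on dim probes (0.0145) and with the intensity trend in the prior variance (0.0333).

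Stress and cell death programmes did not pass either. Targets of p53, which is wild type in this line, had 16 of 27 positive and a median of 0.04 (camera adjusted p = 0.140). The proapoptotic gene PMAIP1, also on the apoptosis list, had 0.27 ± 0.09, DDB2, whose other probe had the opposite sign, -0.13 ± 0.05 and FBXO22 0.11 ± 0.05. Apoptosis regulators had 19 of 28 positive and a median of 0.04 (camera adjusted p = 0.0786), with CASP9 at -0.18 ± 0.06 beside PMAIP1. In the integrated stress response 18 of 27 were positive with a median of 0.07 (camera adjusted p = 0.0931), and DDIT3, or CHOP, had 0.19 ± 0.05 and ATF5, in a disturbed patch, 0.15 ± 0.05. ALDH1L2 of that list was not well above background with the ZNF582-AS1 vector, with a bound of at least 1.42-fold lower. Endoplasmic reticulum chaperone genes had 12 of 21 positive and a median of 0.02 (camera adjusted p = 0.416), with HERPUD1 at 0.13 ± 0.04 and HSPA5 at -0.13 ± 0.05, and EDEM1, in a disturbed patch, was not well above background with the empty vector (at least 1.62-fold higher). Heat shock genes had 13 of 20 positive and a median of 0.06 (camera adjusted p = 0.0786), with HSPA1B at 0.17 ± 0.05, HSPA8 at 0.16 ± 0.06, whose other 2 probes had the opposite sign, and DNAJA1 at 0.15 ± 0.06. NRF2 targets had 12 of 24 positive (camera adjusted p = 0.971), with HMOX1, in a disturbed patch, at 0.17 ± 0.05, GCLM at -0.17 ± 0.05 and ABCC2 at -0.15 ± 0.05. Metallothionein and zinc genes had 6 of 10 positive and a median of 0.02 (camera adjusted p = 0.676), with MT1E at 0.13 ± 0.07, MT1F at -0.11 ± 0.06 and SLC30A1 at 0.07 ± 0.05. Hypoxia and glycolysis genes had 16 of 30 positive (camera adjusted p = 0.945), with ANGPTL4 at -0.24 ± 0.06, ALDOC at -0.16 ± 0.05 and VEGFA, whose other probe had the opposite sign, at 0.19 ± 0.06.

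Lists for responses to introduced nucleic acid were not called. Both groups were transfected with a vector, so a response common to both would not appear in this comparison. Interferon response genes had 13 of 27 positive and a median of -0.03 (camera adjusted p = 0.945), with IFIT5 at 0.14 ± 0.05, IFITM1 at -0.23 ± 0.08 and OAS3 at -0.12 ± 0.05. NF-κB target genes had 9 of 15 positive (camera adjusted p = 0.691), with IRF1 at 0.20 ± 0.04, CXCL3 at -0.13 ± 0.05 and NFKBIA at 0.08 ± 0.05. Antigen presentation genes had 4 of 14 positive and a median of -0.04 (camera adjusted p = 0.945), with PSMB10 at 0.17 ± 0.05, B2M at 0.09 ± 0.06 and HLA-C at -0.11 ± 0.08.

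No list of signalling or identity genes of the line was called. WNT and β-catenin targets had 9 of 15 positive and a median of 0.03 (camera adjusted p = 0.507), with BAMBI at 0.17 ± 0.05, RNF43 at -0.15 ± 0.05 and EPHB3 at -0.21 ± 0.09. YAP and TEAD targets had 10 of 16 positive and a median of 0.03 (camera adjusted p = 0.234), with F3, tissue factor, at 0.25 ± 0.05, WWC1 at 0.23 ± 0.06 and NT5E at 0.19 ± 0.08. Immediate-early and MAPK genes had 16 of 31 positive (camera adjusted p = 0.945), with JUN at 0.22 ± 0.05, PHLDA1 at -0.22 ± 0.06 and EGR1 at -0.14 ± 0.05. Epithelial junction genes had 15 of 28 positive (camera adjusted p = 0.810), with the splicing regulator ESRP1 at -0.21 ± 0.06, TJP3 at -0.35 ± 0.10 and CLDN3 at -0.20 ± 0.06. Mesenchymal genes had 2 of 12 positive and a median of -0.03 (camera adjusted p = 0.810), with ITGA5 at -0.14 ± 0.05, THBS1 at 0.10 ± 0.05 and TWIST1 at 0.14 ± 0.09. Intestinal differentiation genes, of which 11 were measured, had 5 positive (camera adjusted p = 0.575), with CEACAM1 at 0.27 ± 0.05, KRT20, well above background on 1 of 2 empty vector arrays, at 0.61 ± 0.28, and CDX1 at -0.16 ± 0.08. DNA methylation machinery had 12 of 20 positive and a median of 0.06 (camera adjusted p = 0.147), with the demethylation enzyme TET1 at -0.20 ± 0.05, 1 of whose other probes had the opposite sign, TDG at 0.13 ± 0.05 and UHRF2, whose other probe had the opposite sign, at 0.15 ± 0.06. For the NF-κB, hypoxia, intestinal, epithelial junction, immediate-early, interferon and NRF2 lists the median, mean and camera direction did not all have the same sign.

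Genes beside ZNF582-AS1 on chromosome 19 had 2 of 8 measured members positive and a median of -0.06 (camera adjusted p = 0.507), with ZNF787 at 0.12 ± 0.05 and ZNF444 at -0.10 ± 0.06. SMIM17 of this list, not well above background with the ZNF582-AS1 vector, was at least 6.29-fold lower. On its log2 difference of -4.27, which rests partly on background, it passed adjusted over the list alone (limma adjusted p = 0.00921), but not over all genes (0.215). Its probe lay in a disturbed patch, and its other kept probe had the opposite sign and passed as higher (0.52, limma adjusted p = 0.0370) with normexp without spots in patches. Markers of cells that the culture should lack were measured in small numbers. Leukocyte markers had 2 of 8 positive and a median of -0.13 (camera adjusted p = 0.704), with FCER1G at -0.27 ± 0.10, CD14 at 0.24 ± 0.17 and CD79A at -0.14 ± 0.11. Endothelial markers had 1 of 4 positive and a median of -0.11 (camera adjusted p = 0.540), with VWF at -0.12 ± 0.07, EGFL7 at -0.09 ± 0.06 and CDH5 at -0.22 ± 0.22. Fibroblast markers had 1 of 8 positive and a median of -0.13 (camera adjusted p = 0.0786), and were called without empty vector replicate 1 (-0.15, adjusted p = 0.0229), with the collagen genes COL1A1 at -0.36 ± 0.07, COL6A2 at -0.15 ± 0.06 and COL6A1 at -0.11 ± 0.05.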

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

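The tests of clustering on the array and of the neighbours of ZNF582-AS1 were chosen after the pattern had been seen, and the test of other probes of the same genes before its result was seen. Some spots for ERCC control sequences, which take no part in the comparison of genes, were detected in 1 group only. Of 3360 such spots, 4 were well above background on both ZNF582-AS1 vector arrays and on neither empty vector array, and 2 the other way round. Each pair of arrays from different groups alone detected 1 or 2 spots, a count chosen after the result was seen, so a link to the groups is not shown. In all, 38 changed at least 4-fold, each of them flagged as an outlier among its copies by the scanner software on at least 1 array, and 12.4% of the ERCC spots in disturbed patches did so against 0.472% of those outside.

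Most of the largest changes in genes lay in the same kind of patch. Of 29 spots changed at least 4-fold outside the ZNF582-AS1 locus, 65.5% had a neighbour changed likewise, where 95% of 1000 random draws of spots of like brightness gave 0 to 7.07%. Since this clustering is what prompted the test, and patches are defined by varying dim spots nearby, it does not bear out a local disturbance of the array surface, which stays open. For 16 genes a probe in a patch changed at least 2-fold and another probe lay outside patches, well above background on all 4 arrays. These other probes moved by a median of 0.01 (0.00848, 95% bootstrap interval -0.057 to 0.107) where the probes in patches moved by 1.78. For these 16 genes as a set, this argues against a change of the transcripts. The 16 were selected for staying detected on all 4 arrays. Transcripts lost or gained could not enter, so for them the test decides nothing. The 3 probes of the ZNF582-AS1 locus that rose lay outside patches and 1.86 to 4.32 mm apart, so they were not neighbouring spots. The share of varying dim spots near them was 0% for the brightest probe, 11.1% for the second and 20% for XLOC_013167. Dim spots within 150 µm of the 3 probes had a median change of -0.09 (-0.0885, 95% bootstrap interval -0.0904 to -0.0503). A patch needs only a minority of its dim spots to vary. This median could therefore stay small inside a patch too, and it does not decide whether the surface was disturbed there. What set the patches apart, and whether single genes in patches also changed, stays open.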

How the results depend on the processing

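Removal of spots in disturbed patches, alone or with normexp, and scaling on all probes were chosen after seeing the data, and the other alternatives before. The main counts were 3 higher, 1 lower and 2 lists. Higher and lower genes numbered 5 and 6 at an adjusted p under 0.10, 20 and 48 by a 2-fold change with separate groups and no test, 7 and 34 with normexp, 29 and 156 with an intensity trend in the prior variance, 1 and 0 over probes well above background on all 4 arrays, and 0 and 0 without a filter on dim probes, where 36308 genes were tested. Testing every probe gave 2 lower, and normexp without spots in patches gave 56 lower. Same-numbered samples did not deviate together (correlation across genes -0.016), and with the replicate number as a block 0 genes were higher, 0 lower (454 and 1493 at an unadjusted p under 0.05), and ZNF582-AS1 stayed at 6.95 with an adjusted p of 0.172. ZNF582-AS1 had a log2 fold change of 7.02 with quantile normalization (adjusted p = 0.0522) and 6.95 without a filter on dim probes (adjusted p = 0.411), 3.70 with normexp, with or without spots in patches, and 5.94 for the mean of its probes, the range of its adjusted p over alternatives being 7.33e-08 to 0.411. The cause was not tested, except that fewer or more genes were tested with the filters and fewer arrays below. Leaving out each array gave 0 to 2 higher and 0 to 9 lower genes, 2 to 3 lists, and a ZNF582-AS1 log2 fold change of 6.63 to 7.28 (adjusted p = 0.0115 to 0.395, its call lost without either ZNF582-AS1 replicate, at 0.255 and 0.395), with the lone array of a group assumed to vary like the others. Lists called numbered 0 with an estimated correlation, 0 with fry, 1 with quantile normalization, 5 with the intensity trend and 10 without a filter. The trend added the cholesterol synthesis, heat shock and histone lists. Leaving out the filter added these and the apoptosis, DNA methylation, integrated stress response, oxidative phosphorylation and p53 lists. The main calls were shared in full (4 of 4 genes) with normexp, median centring, scaling on all probes, series values and probe means. Among single genes, SMIM17 turned to 0.52 and passed as higher with normexp without spots in patches (adjusted p = 0.0370), where its other probe stood for it. Of 1807 other values of 115 named genes, 1753 kept their status as called or not called, 16 lost and 37 gained the call (those gained mostly under normexp and the intensity trend). Of 522 list values 501 kept that status, 6 lost and 15 gained the call. Signs changed without a call in 6 gene and 42 list values, which are counted among those that kept their status. A slide block was not run, since all arrays lay on 1 slide. Signal over background limits ZNF582-AS1, LINC01622 and the other dim genes to bounds or to estimates that rest partly on background.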

Other observations

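The classes of small nucleolar RNA and of mitochondrial mRNA were chosen after seeing the data, as were the tests of intensity and of histone mRNA for the first; the tests of gene length and of random lists were written before their results were seen. Probes for small nucleolar and Cajal body RNAs, which guide the modification of ribosomal and small nuclear RNA, gave lower signals as a class with ZNF582-AS1. The arrays measured labelled RNA after amplification, so a lower signal is not by itself a lower level of these RNAs. Of 194 such genes measured, 21 were positive, with a median log2 fold change of -0.26 (quartiles -0.47 and -0.15). The groups were separate and lower in 141 and separate and higher in 6. Chance separates 33.3% in all, and 47.7% of all 17065 genes were separate. No member passed in limma over all genes, with 99 lower and 3 higher at an unadjusted p under 0.05, among them SNORA73B (-0.66 ± 0.06, SE, n = 2 per group) and SNORA9 (-0.59 ± 0.05). With normexp 13 members passed, 19 with normexp without spots in patches and 28 with the intensity trend in the prior variance, all lower, and 0 under every other fit; in the fit reported here SNORA12 alone passed at an adjusted p under 0.10, and 6 members were lower by 2-fold with separate groups and no test. Camera gave an adjusted p of 2.98e-25 over the 2 classes, and adjusted p = 0.0322 with an estimated correlation. Since the classes were chosen from these data and the adjustment covers only them, these values do not count as a test of the shift. The median was -0.21 with quantile normalization, -0.24 with median centring, -0.23 with scaling on all probes and -0.19 with normexp. Replicate arrays differed in the class median by 0.03 (empty vector) and -0.04 (ZNF582-AS1 vector). Other noncoding RNAs, picked after seeing the data, ranged in signal from lower to about unchanged. RNU4ATAC had -0.90, RPPH1, the RNA of RNase P, -0.69, RN7SK, in a disturbed patch, -0.61, NEAT1 -0.52 and RMRP -0.37. MALAT1 had -0.23, SNHG1 -0.11, GAS5 -0.07, TERC -0.04 and SNHG5 0.02. Long noncoding RNAs had a median of -0.08 over 677 genes, and protein-coding genes of 0.00 (0.00197) over 12643. With quantile normalization these medians were -0.02 and 0.02.

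An intensity trend between arrays is argued against as the whole cause of the lower small nucleolar RNA signals. Their median log2 fold change minus that of protein-coding genes of like intensity was -0.234 (95% bootstrap interval -0.277 to -0.195). A carry-over that falls with shorter length within the class is argued against too. Across the 194 genes Spearman's rho of gene length and log2 fold change was -0.18 (95% bootstrap interval -0.317 to -0.0419, permutation p = 0.0117), so that the longer ones were lower. It was -0.21 to -0.12 over the 4 pairs of arrays, and genes are not independent replicates. Gene lengths ran from 61 to 421 bases with a median of 128.5, so an even loss of all short RNAs is not excluded by this. Lower yield of RNA without a poly(A) tail stays open: histone mRNAs, which lack one too, had a median of 0.071, but that list differed between replicates by 0.09 and -0.17. The criterion for the histone test was widened to include this spread after its value was seen. A different makeup of the RNA samples of the 2 groups, the position of the arrays on the slide and an effect of ZNF582-AS1 itself may each give such a shift. Position was not separable from group, and with 2 samples per group none of these was tested.

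Protein-coding transcripts of the mitochondrial genome had a median log2 fold change of -0.32 over 12 genes with a probe placed on that genome, of which 1 was positive. COX1, whose probe the file places on chromosome 1, was left out of the class and had -0.39 ± 0.08. ND4 had -0.43 ± 0.06, COX3 -0.40 ± 0.06 and CYTB -0.43 ± 0.07 (SE, n = 2 per group), and ND6, the mRNA read from the other strand, had 0.26 ± 0.06. No member passed in limma over all genes, while 2 passed with normexp, 3 with normexp without spots in patches and 7 with the intensity trend, all lower. For this class, also chosen from these data, camera gave an adjusted p of 1.27e-06, and adjusted p = 0.241 with an estimated correlation. Replicate arrays differed by 0.08 and -0.10 in the class median.

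An intensity trend is argued against for the higher ribosome biogenesis and G1/S lists, whose medians each lay at the 99.9th percentile of 10000 random lists of protein-coding genes matched on intensity (medians of the random lists 0.02 and 0.02). Replicate arrays differed in the median of the ribosome biogenesis list by 0.00 (0.000654 and 0.00119), against 0.07 between groups, and in that of the G1/S list by -0.02 and 0.02, against 0.06 between groups, or 0.03 without empty vector replicate 2. Whether the shift is one of the cells, of the RNA samples or of array position, which was not separable from group, stays open. The estimated correlation and fry ended both calls, and no biological explanation was tested.

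Control probes for E1A, which carry graded signals independent of the cells' genes, had a median log2 fold change of 0.02 over 10 probes on the same scale, with a range of -0.07 to 0.06. The value of -0.07 came from a probe with a mean log2 signal of -8.62. That is under -6.63, the mean over arrays of the lowest signal among probes well above background, so the range rests partly on background.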
